A study of Mus musculus with 24 samples.

How the data were processed

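The series holds 24 samples of mIMCD3 mouse kidney cells: 12 RNA-seq libraries and 12 ChIP-seq, immunoglobulin and input libraries. RNA-seq values are raw counts of reads per Ensembl gene, deposited by the authors as 1 table of 47068 genes and 12 libraries. Per the labels, FastQC, HISAT2, Subread, BWA, MACS2 and the GRCm38 build were used, without versions or the role of each tool, and the annotation is not stated. Peak lists were made with MACS2 2.1.1.20160309 in broad mode per the file headers, with q limits of 0.05 and 0.1, from single-end tags of 51 bp with 1 tag kept per position. For each genotype 2 Wnt3a β-catenin ChIP libraries were pooled as treatment against 2 pooled mock ChIP libraries, again per the file headers. The lists give, per the file headers, the pileup, a signal of extended treatment tags, and the fold enrichment, a ratio of the Wnt3a ChIP over the local mock background. They also give the -log10 p-value and -log10 q-value of each peak and its length in bp, an other unit that the authors deposited beside the scores. Filtered treatment tags numbered 70.8 M in deficient and 64.0 M in WT cells, and control tags 71.6 and 71.0 M. The caller's fragment length was 51 bp in deficient and 46 bp in WT cells, no longer than about the tag itself, so peak widths and pileups rest on the tags alone. Per-library ChIP, immunoglobulin and input values were not analysed here.

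Samples were grouped from the labels by genotype and treatment before the data were examined, and so were the comparisons, the tests, most of the alternatives, 27 gene lists with 542 genes and the rule for naming genes. Genes were tested in edgeR 4.0.16 on the deposited counts, with TMM factors, filterByExpr on the groups, a model of 4 group means over all 12 libraries, the quasi-likelihood F-test and Benjamini-Hochberg adjustment at 0.05. The filter kept 15994 genes. Library totals ran from 22.5 to 33.4 M. Gene lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1, with a preset correlation of 0.01 on log2 CPM with a prior count of 2. They were tested again by camera with an estimated correlation and by fry, which asks whether the genes of a list move one way and does not compare them with other genes. Where a group had 0 counts, a lower bound of the fold was taken at a floor of 3 counts over the group. Where it had 1 to 3 counts, a ratio with an exact 95% interval was used. These cover counting error only.

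The naming rule took Hnf1b, Axin2, Ccdc80 and Rnf43 in every comparison, and the 5 genes with the largest rise and fall, a mean log2 CPM of at least 1 and no overlap between groups. By chance 10% of genes separate 3 libraries from 3. It also took 4 members with the smallest adjusted p from each list that passed or had at least 3 called members, 8 for 2 lists, and 1 from the others. The text names a part of the genes the rule allows. Symbols were joined by Ensembl identifier, and 98.8% of identifiers had one. Positions came from the RefSeq annotation of GRCm38 and covered 92.3% of tested genes. Distances from peaks to transcription start sites had been planned, but the table of positions holds no strand, so the distance to the gene's interval, within 50 kb, was chosen after the reference was seen. Peaks and called genes were compared by Fisher's exact test, two-sided, over the 14765 tested genes with a position, and by circular shifts.

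The pipeline was tested on simulated data: with planted 2-fold changes it recovered 74.6% in the WT Wnt3a comparison and 59.7% in the difference of responses, with 7 false among 169 calls and 6 among 143. For the comparisons that share WT mock libraries, 50 sets of unchanged groups were drawn from negative binomial counts around the mock means, with the mock libraries drawn anew. This form was chosen after a first one, which kept the mock libraries and gave a mean covariance of 0.000492. Groups drawn around the mean of kept libraries share no chance value with them. Alternatives were RLE and upper quartile factors, no filter or CPM of at least 1 in 3 libraries, a 2-fold limit, glmTreat against 1.2-fold, DESeq2 1.42.0, a replicate block, the 6 libraries of a comparison alone, leaving out each library, and other peak limits. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Motifs in peaks were not analysed here, since no genome sequence was at hand.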

Results

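mIMCD3 is a mouse cell line derived from the inner medullary collecting duct of the kidney. The series compared wild-type (WT) cells with cells deficient in hepatocyte nuclear factor-1β (HNF-1β), a homeodomain transcription factor of kidney tubule epithelium encoded by Hnf1b. Cells of both genotypes received Wnt3a, a ligand of the canonical Wnt pathway, at 100 ng/ml for 16 h, or a mock treatment. Polyadenylated RNA was sequenced in 12 libraries, 3 for each of 4 groups. Binding of β-catenin, the transcriptional coactivator of that pathway, was measured by chromatin immunoprecipitation (ChIP) in 8 libraries, 2 per group, beside 2 immunoglobulin controls and 2 inputs. The RNA libraries held 22.5 to 33.4 M counted reads, with 22.5 to 25.9 M in WT and 24.3 to 33.4 M in deficient cells. The first principal component of log2 expression carried 70% of the variance and parted the genotypes, and the second carried 9.62% and parted Wnt3a from mock libraries within each genotype. The labels do not say whether replicates were separate cultures or how many deficient clones were used, so genotype and cell line cannot be told apart.

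Hnf1b, the gene targeted in the deficient cells (ENSMUSG00000020679, GRCm38 chromosome 11, 83850209 to 83905917), was read in every library. The WT mock libraries held 107, 105 and 117 CPM (library-size scaled counts, edgeR cpm), and the deficient mock libraries 38.5, 38.3 and 39.7. Under Wnt3a the group means were 114 ± 4.10 CPM in WT and 49.1 ± 0.694 CPM in deficient cells (SD, n = 3). Hnf1b fell by 1.5 ± 0.05 on the log2 scale between mock groups (approximate SE, adjusted p = 1.4e-12). Between Wnt3a groups it fell by 1.22 ± 0.05 (adjusted p = 9.1e-12). In WT cells no change with Wnt3a was detected (log2 fold change 0.05 ± 0.05, adjusted p = 0.66), while in deficient cells it rose by 0.34 ± 0.05 (adjusted p = 8.6e-05). In all comparisons, the ± of a log2 fold change is its size divided by the square root of the test's F statistic. This approximates an SE and can be too small for large folds that rest on few counts. CPM carry the SD of 3 libraries. Adjusted p-values come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested.

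**Figure D1:**
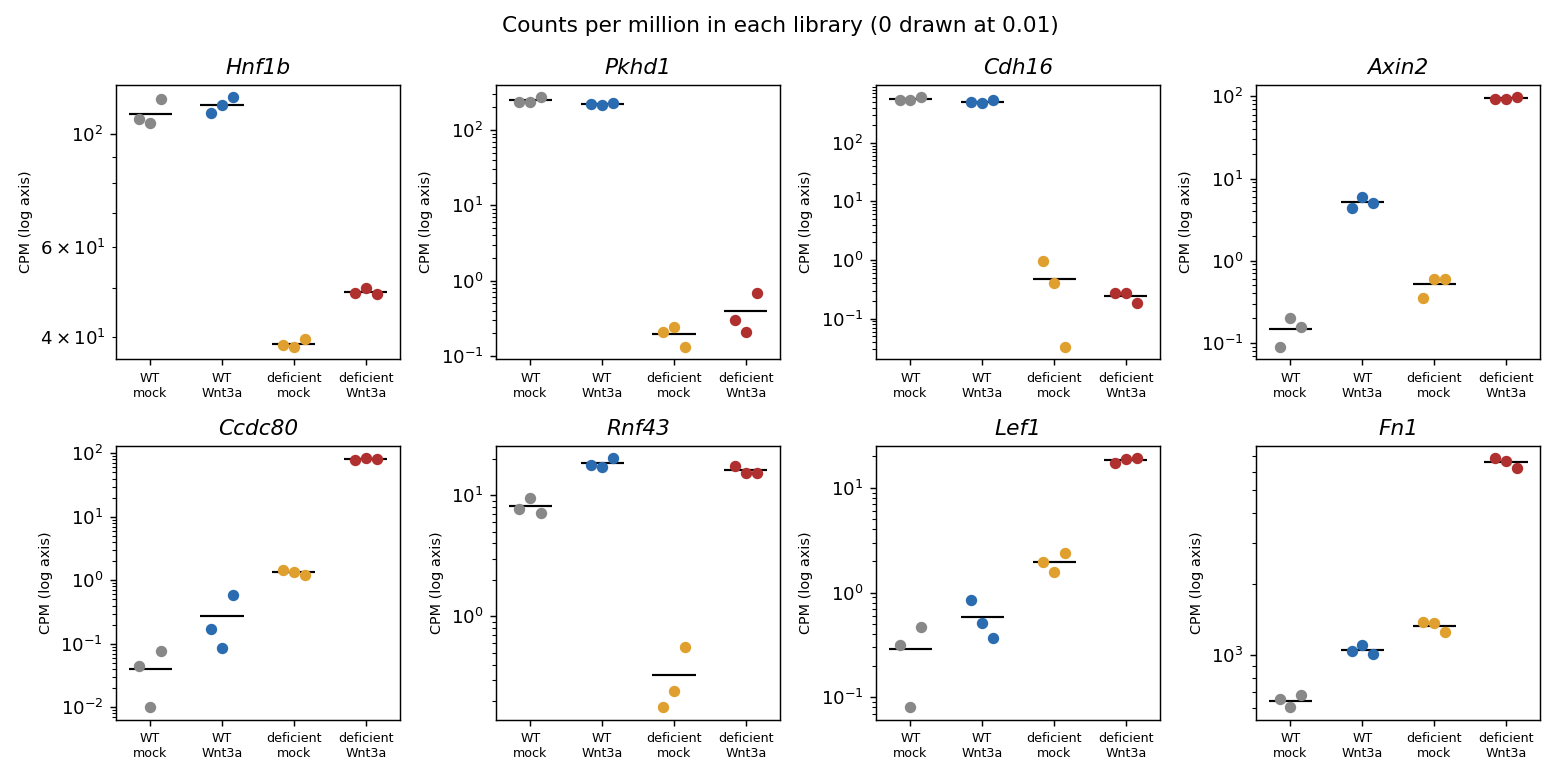
Expression of 8 genes in the 12 RNA-seq libraries, in CPM on a log axis; each point is 1 library, lines are group means of 3 libraries, and values of 0 are drawn at 0.01. Hnf1b means fell from 110 CPM in WT mock to 38.8 CPM in deficient mock cells, and Axin2 means were 5.14 CPM in WT and 94.3 CPM in deficient cells under Wnt3a.

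The first comparison asked what differs between deficient and WT cells without added Wnt3a. The kidney epithelial genes Pkhd1, Cdh16 and Kif12 were far lower in deficient cells. Pkhd1, which encodes the cystic disease protein fibrocystin (chromosome 1, 20057779 to 20618082), fell from 248 ± 20.6 to 0.194 ± 0.0557 CPM (log2 fold change -10.31 ± 0.17, adjusted p = 1.0e-15). Collagen and other mesenchymal genes were higher: Col1a1, a fibrillar collagen chain, rose from 2.21 ± 0.147 to 53.6 ± 1.58 CPM (log2 fold change 4.59 ± 0.11). In all, 9056 of 15994 genes tested passed, 4457 higher and 4599 lower, and 2688 of them differed at least 2-fold. Among the genes that met the naming rule, the largest decreases included the kidney cadherin Cdh16 (-10.14), the kinesin gene Kif12 (-10.24) and Prom1, the gene of prominin 1 (-9.60). The transcript ccdc198 was listed at 0 counts in all 3 deficient mock libraries against 5971 in WT, which makes it at least 2422-fold lower at a floor of 3 counts over the group. The largest increases by the same rule included the heparan sulfate 6-O-endosulfatase gene Sulf2 (7.84), the angiopoietin gene Angpt4 (7.58), the proteoglycan decorin gene Dcn (7.44), the atypical cadherin gene Fat4 (7.41) and the transcriptional coactivator gene Eya4 (7.19). Single libraries moved some of these folds by over 1.5 times, with the calls kept. Without deficient mock replicate 2 the Kif12 value was -11.25, without deficient mock replicate 1 the Cdh16 value was -11.40, and without WT mock replicate 3 the Eya4 value was 8.04.

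Of 19 tested members of a list of HNF-1β target genes, 14 fell, 4 rose and 1 did not pass, with the same counts adjusted over the list alone. The list ranked lower than other genes by camera (adjusted p = 9.2e-05), a call lost with an estimated correlation (adjusted p = 0.061 with an estimated correlation). Besides Pkhd1, Cdh16 and Kif12, the falls covered the cholesterol-regulating protease Pcsk9 (-7.61), the dipeptidyl peptidase Dpp4 (-8.17), the cadherin gene Cdh6 (-4.66) and the RNA-binding protein gene Bicc1 (-1.66). Of 28 mesenchymal genes, 23 rose, 2 fell and 3 did not pass, also when adjusted over the list alone (camera adjusted p = 1.6e-09, and 0.0018 with an estimated correlation). Col5a1 (3.06) and the matrix glycoprotein gene Sparc (1.62) rose, and Col3a1, at 0 counts in WT mock, was at least 661-fold higher. All 4 tested fibroblast and pericyte markers rose, as when adjusted over the list alone, among them Pdgfrb, at least 55.0-fold above its 0 counts in WT; the labels name no other cell type in these cultures. Of 24 epithelial genes, 18 fell and 3 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.00043, but adjusted p = 0.12 with an estimated correlation). Keratin genes Krt8 (-2.34) and Krt19 (-2.82) and the polarity gene Crb3 (-4.38) fell, and the tight junction gene Cldn1 rose (3.89). Of 4 proximal tubule markers 3 rose, as when adjusted over the list alone, among them the water channel gene Aqp1 (3.04). Of 6 principal cell markers 3 rose and 1 fell, and 3 and 2 adjusted over the list alone (camera adjusted p = 0.72).

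Wnt pathway lists were also compared between the mock groups, where 56.6% of all tested genes passed. Of 27 core genes of the pathway 15 rose and 5 fell, and 15 and 6 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.062). Of 25 Wnt ligands and receptors, 15 rose and 3 fell, as when adjusted over the list alone (camera adjusted p = 0.0032, but adjusted p = 0.13 with an estimated correlation). The receptors Fzd2 (1.99) and Fzd6 (1.23) rose and Fzd5 (-1.5) fell. All 5 tested members of a list of secreted Wnt antagonists rose, though not all of the 5 encode secreted proteins. The result was the same adjusted over the list alone (camera adjusted p = 0.0074, but adjusted p = 0.12 with an estimated correlation). Among the 5 were Igfbp4 (5.24) and Sfrp1, whose fit rested on few WT counts: 6.25, or 10.48 without WT mock replicate 3. Of 30 Wnt/β-catenin target genes, 13 rose and 6 fell, 14 and 6 adjusted over the list alone, and the list did not pass as a whole (camera adjusted p = 0.21). Axin2, a negative regulator of β-catenin (chromosome 11, 108917828 to 108950783), rose from 0.148 ± 0.0555 to 0.519 ± 0.142 CPM (1.72 ± 0.37, adjusted p = 0.001). Bmp4, a secreted growth factor gene, rose (2.52), and Rnf43, a ubiquitin ligase that removes Wnt receptors (chromosome 11, 87663087 to 87735539), fell by 4.61 ± 0.25, or by 5.27 without deficient mock replicate 3. The transcription factor gene Irx3 fell (-5.31). Ccdc80, which encodes a secreted matrix protein (chromosome 16, 45093407 to 45127924), had 3 counts in WT mock and 119 in deficient mock libraries. The ratio was 32.6 with a 95% counting interval of 10.9 to 160.0, and leaving out WT mock replicate 3 moved the fitted fold 1.78-fold.

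Several stress and metabolic lists were lower in deficient mock cells, and none of these calls held with an estimated correlation. Of 16 hypoxia and glycolysis genes 14 fell, 15 adjusted over the list alone (camera adjusted p = 7.1e-08, but adjusted p = 0.15 with an estimated correlation). The glycolytic enzyme genes Aldoa (-2.02) and Pgk1 (-2.27) and the hypoxia-induced Ndrg1 (-1.75) were among them. Of 16 unfolded protein response genes 13 fell, as when adjusted over the list alone, including the stress transcription factor gene Ddit3 (-2.92) and Herpud1 (-2.76), a gene of endoplasmic reticulum protein degradation (camera adjusted p = 0.00043, but adjusted p = 0.47 with an estimated correlation). Of 22 interferon response genes 18 fell and 1, Ifit2 (1.14), rose, as when adjusted over the list alone; the interferon regulatory factor gene Irf7 fell by 1.49 and the interferon-signalling inhibitor gene Usp18 by 2.15 (camera adjusted p = 9.9e-05, but adjusted p = 0.24 with an estimated correlation). Of 24 cholesterol synthesis and uptake genes 15 fell and 2 rose, as when adjusted over the list alone (camera adjusted p = 0.0052, but adjusted p = 0.40 with an estimated correlation), with Fdps, an isoprenoid synthesis enzyme gene (-0.94), and the sterol transfer gene Stard4 (-1.34) among the falls. Of 5 intercalated cell markers 4 fell, as when adjusted over the list alone, including carbonic anhydrase 2, Car2 (-2.28; camera adjusted p = 0.01, but adjusted p = 0.12 with an estimated correlation). Genes of chromosome 18 were lower as a group (median log2 fold change -0.52 over 296 genes), and those of chromosome 16 higher (0.44 over 364 genes). Without both chromosomes, 8425 genes passed.

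**Figure D2:**
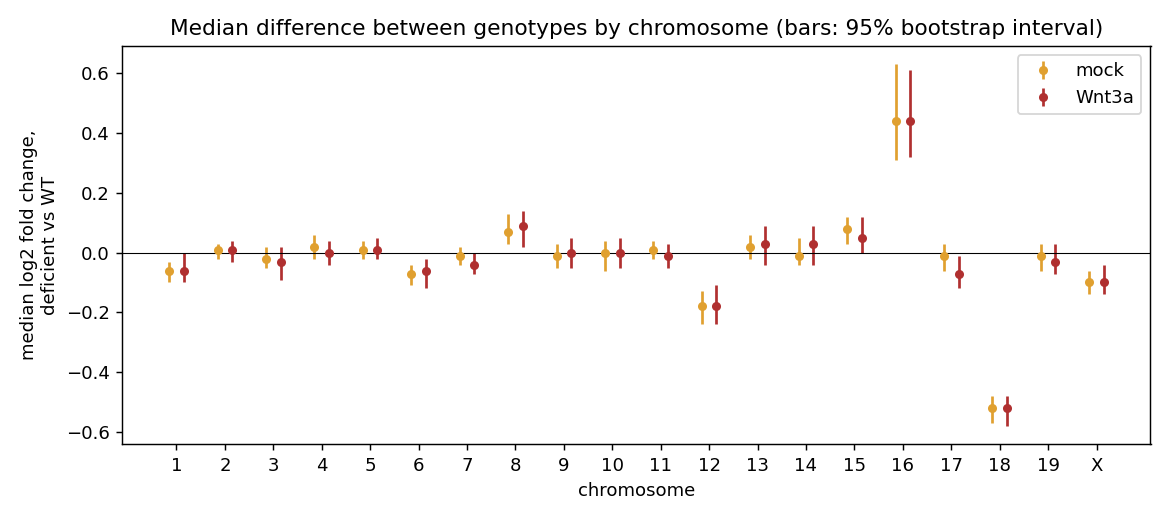
Median log2 fold change between deficient and WT cells for the genes of each chromosome, in mock (orange) and Wnt3a (red) cells; bars are 95% bootstrap intervals over genes. Chromosome 18 lies at -0.52 and chromosome 16 at 0.44 in mock cells.

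**Figure D3:**
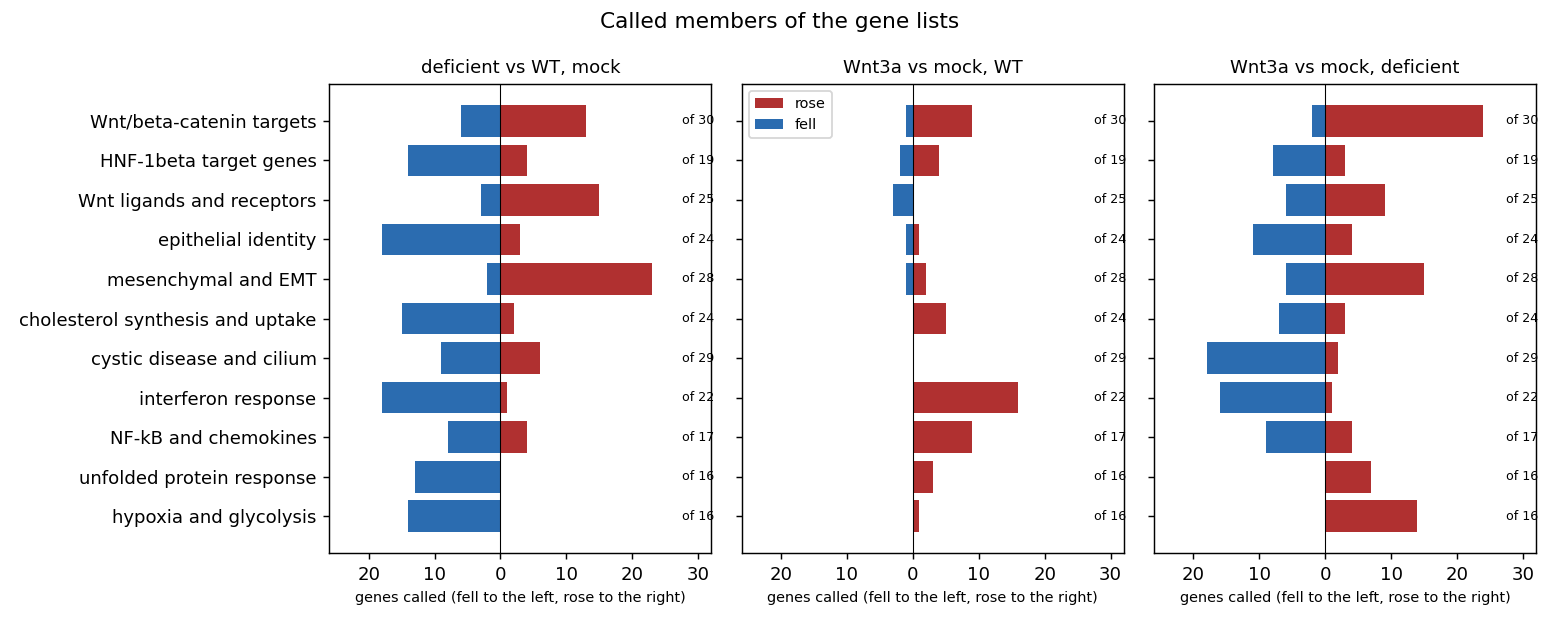
Number of members of 11 gene lists that rose (red, to the right) or fell (blue, to the left) in 3 comparisons, by the edgeR test over all genes; the number at the right of each row is the number tested. Interferon response genes mostly fell in deficient mock cells (18 of 22), rose with Wnt3a in WT cells (16 of 22) and fell with Wnt3a in deficient cells (16 of 22).

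The second comparison asked how WT cells respond to Wnt3a. Part of the classical target genes rose, and so did most interferon response genes and part of the NF-κB targets and chemokines. Axin2 rose from 0.148 ± 0.0555 to 5.14 ± 0.850 CPM (log2 fold change 5.05 ± 0.24, adjusted p = 9.7e-09). Of 15994 genes, 657 passed, 363 higher and 294 lower, and 71 changed at least 2-fold, 56 higher and 15 lower. Without WT mock replicate 2 the count was 428. Of 30 Wnt/β-catenin targets, 9 rose and 1 fell, and 12 and 2 adjusted over the list alone (camera adjusted p = 8.3e-07, and 0.0037 with an estimated correlation). Axin2, Ccdc80 and Rnf43 were put on this list from knowledge of the study and are no independent evidence; without them the adjusted p was 0.00013. The stem cell receptor gene Lgr5 rose by 4.02 ± 0.49, or by 5.15 without WT mock replicate 3. The transcription factor genes Sp5 (3.73), Tcf7 (0.57) and Sox9 (0.79) rose, as did Bmp4 (0.66) and Rnf43 (1.19 ± 0.16, adjusted p = 0.00033). Znrf3, a relative of Rnf43, passed at 0.31 ± 0.08 (adjusted p = 0.032) but in only 1 of 6 fits that left out 1 library, where its adjusted p ran from 0.026 to 0.14. That 1 fit left out WT mock replicate 3. Ccdc80 went from 3 to 20 counts, a ratio of 6.84 with a counting interval of 2.03 to 36.0, and did not pass (adjusted p = 0.076). It passed with DESeq2 (adjusted p = 0.032) and without WT Wnt3a replicate 2 (adjusted p = 0.024), in a range of 0.024 to 0.46 over leave-one-out fits.

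Of 22 interferon response genes, 16 rose and none fell in WT cells, and 19 rose adjusted over the list alone (camera adjusted p = 5.1e-24, and 0.013 with an estimated correlation). Ifi44 (1.61), the ubiquitin-like gene Isg15 (1.09), the tetherin gene Bst2 (0.76), Usp18 (0.93) and Rtp4 (1.2) were among them. Of 17 NF-κB targets and chemokines 9 rose and 12 rose adjusted over the list alone, with none falling (camera adjusted p = 5.3e-13, and 0.0015 with an estimated correlation). The chemokine genes Ccl2 (1.15) and Cxcl1 (1.04), the cytokine gene Csf1 (0.57) and the complement gene C3 (0.65) rose. Of 15 immediate early genes 4 rose, Junb (0.50) among them, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00023, and 0.026 with an estimated correlation). Of 24 cholesterol genes 5 rose, 11 adjusted over the list alone, including the sterol demethylase gene Cyp51 (0.27) and Msmo1 (0.30; camera adjusted p = 8.3e-07, but adjusted p = 0.23 with an estimated correlation). Of 16 unfolded protein response genes 3 rose, over all genes and adjusted over the list alone, with Atf3 at 0.74 (camera adjusted p = 0.026, but adjusted p = 0.60 with an estimated correlation). Other increases included the growth factor gene Tgfb2 (3.08), fibronectin, Fn1 (0.71), the cytochrome gene Cyp1b1 (1.95), the transcription factor gene Arnt2 (1.94) and the laminin gene Lama1 (0.99). The GDNF receptor gene Gfra1 (-1.16), Anxa8 (-1.36), Dhrs9 (-1.25), Akr1c14 (-1.13), Wnt4 (-1.03) and vimentin, Vim (-0.39), fell. Zfp992 fell as well (-2.90 ± 0.55), but it belongs to a multi-copy zinc finger family, which leaves the assignment of its reads uncertain.

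The third comparison asked the same of deficient cells, in which many more genes passed: 4987 of 15994, 2502 higher and 2485 lower, with 955 changed at least 2-fold. With upper quartile factors the balance was 2071 higher and 2905 lower. Axin2 rose from 0.519 ± 0.142 to 94.3 ± 2.58 CPM (log2 fold change 7.52 ± 0.14, adjusted p = 7.1e-14). Ccdc80 rose from 1.33 ± 0.112 to 80.9 ± 3.01 CPM (5.91 ± 0.17) and Rnf43 from 0.328 ± 0.207 to 16.0 ± 1.31 CPM (5.60 ± 0.24). Leaving out deficient mock replicate 3 raised the Rnf43 value to 6.25. Of 30 Wnt/β-catenin targets, 24 rose and 2 fell, and 25 and 2 adjusted over the list alone (camera adjusted p = 5.8e-12, and 0.00076 with an estimated correlation); without Axin2, Ccdc80 and Rnf43 the adjusted p was 2.4e-09. Lef1, the DNA-binding partner of β-catenin, rose from 1.97 ± 0.409 to 18.4 ± 1.17 CPM (3.21 ± 0.24). Irx3 (2.71), the Wnt inhibitor gene Apcdd1 (2.05), the transcription factor gene Twist1 (1.36) and the receptor gene Lgr6 (0.82) rose as well. Of 25 Wnt ligands and receptors 9 rose and 6 fell, as when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.33). The ligand genes Wnt6 (3.25), Wnt7b (3.09) and Wnt9a (3.04) rose. Outside these lists the retinoic acid synthesis gene Aldh1a2 (5.36), Tent5c (4.95) and the ubiquitin ligase gene Rnf152 (4.53, or 5.22 without deficient mock replicate 3) rose most among the genes that met the naming rule. By the same rule, falls were largest for the aminopeptidase gene Enpep (-4.65), Ttc22 (-4.04), the small GTPase gene Rasl11a (-3.87), the kinase gene Cdkl1 (-3.79, or -4.40 without deficient Wnt3a replicate 3) and the CSF1 receptor gene Csf1r (-3.52).

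Of 28 mesenchymal genes 15 rose and 6 fell in deficient cells under Wnt3a, as when adjusted over the list alone (camera adjusted p = 0.0053, but adjusted p = 0.053 with an estimated correlation). Fn1 rose from 1338 ± 77.8 to 6567 ± 319 CPM (2.30 ± 0.06), and Tgfb2 (3.64), Mmp14, a membrane-bound metalloproteinase gene (1.23), and the matricellular gene Ccn2 (1.16) rose. Of 4 fibroblast and pericyte markers 3 fell, Dcn (-3.03) among them, and 1 rose, as when adjusted over the list alone. Of 29 cystic disease and cilium genes 18 fell and 2 rose, and 19 and 2 adjusted over the list alone (camera adjusted p = 8.3e-05, but adjusted p = 0.053 with an estimated correlation). The falls were small, as for the nephronophthisis gene Nphp1 (-0.36) and the ciliary trafficking gene Bbs1 (-0.46), and Glis3 rose (0.55). Of 16 hypoxia and glycolysis genes 14 rose, and 14 rose and 1 fell adjusted over the list alone, with the hexokinase gene Hk2 at 1.36 and Bnip3 at 1.28 (camera adjusted p = 4.4e-05, but adjusted p = 0.27 with an estimated correlation). Of 16 unfolded protein response genes 7 rose, as when adjusted over the list alone, with Chac1 at 1.16 (camera adjusted p = 0.0046, but adjusted p = 0.63 with an estimated correlation). Of 22 interferon response genes 16 fell and 1, Cxcl10 (0.88), rose, as when adjusted over the list alone; Irf7 (-1.07) and Ifit2 (-0.73) fell (camera adjusted p = 1.2e-05, but adjusted p = 0.22 with an estimated correlation). Of 17 NF-κB targets and chemokines 9 fell and 4 rose, as when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.086), with C3 (-2.04) and Cxcl5 (-2.79) among the falls. Of 5 intercalated cell markers 4 fell, as when adjusted over the list alone, Car2 by 1.51 (camera adjusted p = 0.028, but adjusted p = 0.20 with an estimated correlation). The desmosome gene Dsp fell (-0.90) and the claudin gene Cldn4 rose (3.21).

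The responses of the genotypes were then set against each other. Of the 363 genes raised by Wnt3a in WT cells, 229 (63.1%) were also raised in deficient cells, against 56.8 if calls were independent (odds ratio 10.0, Fisher's exact test, two-sided, p = 8.5e-96). Of the 294 lowered, 220 (74.8%) were also lowered, against 45.7 (odds ratio 17.6, exact p = 1.6e-116). A further 81 genes passed in opposite directions, against 102 if independent. These tests run across genes, which are not independent replicates. Over 12090 genes the log2 fold changes had a Pearson correlation of 0.38 and a Spearman correlation of 0.39, across genes.

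A direct test of the difference in response, deficient minus WT, called 2131 genes, 1059 with a higher and 1072 with a lower value in deficient cells (922 and 1229 with upper quartile factors), and 533 of them differed at least 2-fold. Axin2 rose more in deficient cells (difference 2.48 ± 0.51, adjusted p = 0.0038), as did Rnf43 (4.41 ± 0.30, adjusted p = 9.6e-08, and 5.06 without deficient mock replicate 3). Rnf43 started lower in deficient than in WT mock cells (-4.61). Under Wnt3a no difference in Rnf43 between the genotypes was detected (-0.20 ± 0.15, adjusted p = 0.26). Ccdc80 did not pass (adjusted p = 0.14). It passed with DESeq2 (adjusted p = 0.0058) and without WT Wnt3a replicate 3 (adjusted p = 0.014), in a range of 0.014 to 0.57 over leave-one-out fits. The difference for Hnf1b itself was 0.28 ± 0.07 (adjusted p = 0.012). Of 30 Wnt/β-catenin targets 12 had a higher and 2 a lower difference, and 15 and 3 adjusted over the list alone (camera adjusted p = 1.1e-07, and 0.0046 with an estimated correlation). Without Axin2, Ccdc80 and Rnf43 the adjusted p was 1.7e-05. Irx3 (2.99) and Apcdd1 (1.78) had higher values and the helix-loop-helix gene Id2 (-1.15) a lower one. Of 28 mesenchymal genes 10 had a higher and 1 a lower value, and 11 and 2 adjusted over the list alone (camera adjusted p = 0.0021, and 0.022 with an estimated correlation), with Fn1 (1.58) and the smooth muscle gene Tagln (3.07) among them. Of 22 interferon response genes 18 had a lower and 1 a higher value, and 19 and 1 adjusted over the list alone (camera adjusted p = 2.9e-18, and 0.022 with an estimated correlation). Ifi44 (-4.54) and Irf7 (-2.00) had lower values. Of 17 NF-κB targets and chemokines 10 had a lower and 1 a higher value, and 11 and 1 adjusted over the list alone (camera adjusted p = 1.1e-07, and 0.0049 with an estimated correlation), Ccl2 (-1.51) among them.

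Among cystic disease and cilium genes 10 of 29 had a lower and 1 a higher difference, and 16 and 2 adjusted over the list alone (camera adjusted p = 6.6e-05, and 0.022 with an estimated correlation). Of 24 cholesterol genes 7 had a lower value, 10 adjusted over the list alone, including the sterol sensor gene Insig1 at -0.53 (camera adjusted p = 0.0002, but adjusted p = 0.33 with an estimated correlation). Of 16 hypoxia and glycolysis genes 6 had a higher value, 8 adjusted over the list alone, with Hk2 at 1.0 (camera adjusted p = 0.00016, but adjusted p = 0.35 with an estimated correlation). Of 5 intercalated cell markers 3 had a lower value, as when adjusted over the list alone (camera adjusted p = 0.022, but adjusted p = 0.13 with an estimated correlation). HNF-1β target genes did not pass as a list (3 higher and 4 lower of 19, 4 and 6 adjusted over the list alone, camera adjusted p = 0.22). Cdh6 had a higher value (1.74), while the potassium channel gene Kcnj16 (-1.41) and the transpeptidase gene Ggt1 (-1.36) had lower ones.

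**Figure D4:**
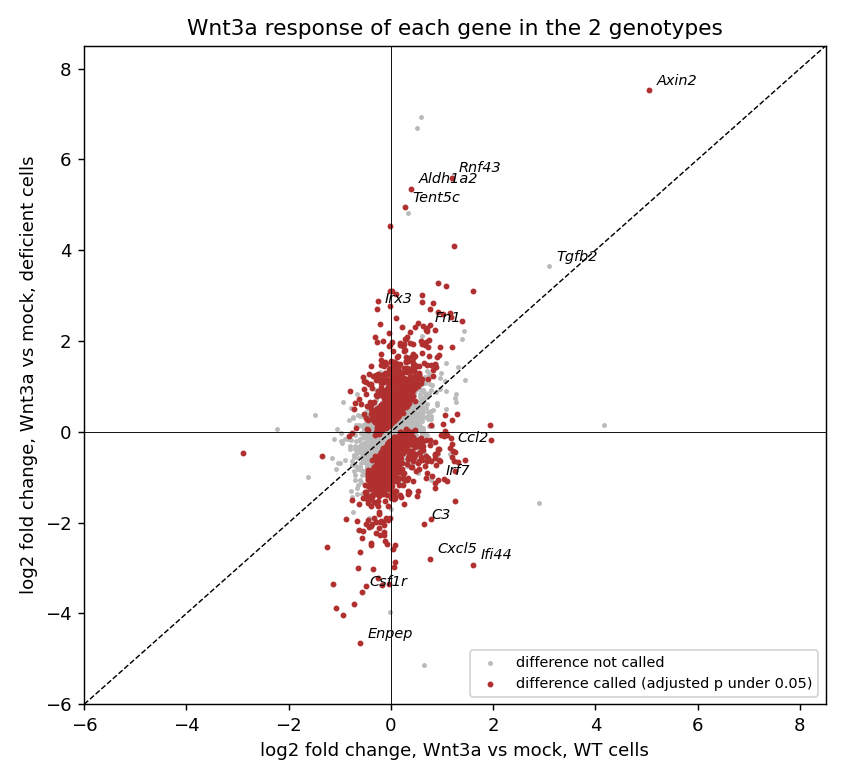
Log2 fold change with Wnt3a in WT cells (x axis) against that in deficient cells (y axis), 1 point per gene; red points are the genes whose responses differ by the edgeR test, and the dashed line marks equal responses. Axin2 lies at 5.05 and 7.52, and Rnf43 at 1.19 and 5.60.

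The genotypes were also compared under Wnt3a. Here 9701 of 15994 genes passed, 4781 higher and 4920 lower, and 3118 differed at least 2-fold. Axin2 was higher in deficient cells (4.20 ± 0.11) and so was Ccdc80 (8.14 ± 0.22, or 9.26 without WT Wnt3a replicate 3), whereas Rnf43 did not pass (-0.20 ± 0.15, adjusted p = 0.26). Of 30 Wnt/β-catenin targets 20 were higher and 5 lower, as when adjusted over the list alone (camera adjusted p = 0.0018, and 0.033 with an estimated correlation). Apcdd1 was higher (4.04), although it lies on chromosome 18, whose genes were lower as a group (median -0.52). Of 19 HNF-1β targets 15 were lower and 4 higher, as when adjusted over the list alone (camera adjusted p = 3.6e-05, and 0.033 with an estimated correlation). Pkhd1 was at -9.08 ± 0.16, or -9.72 without deficient Wnt3a replicate 3, and Kif12, listed at 0 counts in deficient Wnt3a libraries, was at least 2649-fold lower. Of 22 interferon response genes 21 were lower and 1 higher, as when adjusted over the list alone (camera adjusted p = 1.0e-09, but adjusted p = 0.067 with an estimated correlation), including Irf7 (-3.48) and Usp18 (-3.46). Fn1 (2.64) was higher, and Krt8 (-2.68), C3 (-4.79) and Csf1r (-6.07) were lower. The growth factor activator gene Hgfac had 3 counts in deficient and 3607 in WT libraries, a ratio of 1540 with a counting interval of 527 to 7480, and its fitted fold moved 1.80-fold without deficient Wnt3a replicate 2. The amine oxidase gene Aoc1 was lower (-9.84, or -9.24 without deficient Wnt3a replicate 3). Angptl2 (6.40), the neuronal cytoskeleton gene Dpysl3 (6.23) and the myelin protein gene Pmp22 (7.57, or 8.28 without WT Wnt3a replicate 1) were higher.

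Genes that differed between deficient and WT mock cells were set against those changed by Wnt3a in WT cells, and both comparisons use the 3 WT mock libraries. There were 177 genes higher in both and 148 lower in both, against 101 and 84.5 if calls were independent, and 225 in opposite directions against 186. With the mock libraries split between the comparisons, 1 against 2 in all 6 ways, 98 to 274 genes changed in the same direction in both. They gave 69 to 150 genes higher in both against 41.3 to 81.1 if independent, 29 to 124 lower against 19.1 to 60.3, and 91 to 217 opposite against 61.5 to 143. In every split the counts lay above the value for independent calls in both shared directions, and so did the opposite calls. An excess was therefore not limited to genes changed in the same direction. In each split 1 comparison rests on a single mock library, with the spread taken from the other groups, so these counts are uncertain. The covariance of the log2 fold changes across genes was 0.0318 (correlation 0.165) with shared controls and 0.00117 to 0.022 (0.0038 to 0.0956) with split ones. In 50 simulations of unchanged groups, mock libraries included, the covariance averaged 0.0125, with 0.0184 the highest. The observed value covers genes with a mean log2 CPM of at least 1 over all 12 libraries. The simulated one covers genes at that level around the WT mock means, which leaves out genes near 0 in WT mock cells. Those genes have the largest counting error, so the simulated covariance may be too low to set against the observed one. The simulated correlation averaged 0.493 (0.362 to 0.608), above the observed one, but correlations with and without real effects are not on 1 scale. At most 4 genes passed in a simulated comparison, so these give no useful chance value for the number of shared genes. Part of the excess of 177 and 148 over independent calls may come from the shared controls.

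The β-catenin peak lists asked where binding rose with Wnt3a. Each list compares pooled Wnt3a with pooled mock ChIP of 1 genotype, so a region bound equally in both is absent from it. The deficient-cell list held 1122 peaks and the WT list 201. Of the WT peaks, 130 (64.7%, 95% exact Clopper-Pearson interval 57.6 to 71.3) overlapped a deficient-cell peak by at least 1 bp, and these covered 11.6% of the deficient-cell list. In 200 circular shifts of the WT peaks, without the mitochondrial ones, the overlap averaged 0.04 and never exceeded 1. Peaks this short seldom meet at shifted places, so the shifts do not tell shared binding from shared artefacts. The overlap was 33.3% when at least 50% of each peak had to be shared. With 1 list per genotype the difference in peak number has no replicate error and was not tested.

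Among 39 Wnt/β-catenin targets with a position, 10 had a deficient-cell peak within 50 kb and 4 a WT peak. At Axin2 the deficient-cell list held 6 peaks and the WT list none. Fold enrichments and q-values of peaks are the authors' own. The highest-scoring of the 6 lay inside the gene at 108920211 to 108920503 on chromosome 11, with a fold enrichment of 4.56 and a -log10 q of 3.51. At Rnf43 the lists shared 2 places inside the gene. At 1 of them a deficient-cell peak lay at 87678597 to 87679386 (fold enrichment 5.74) and a WT peak at 87679180 to 87679245 (4.39). The other lay at 87689396 to 87689751 in deficient cells (fold enrichment 4.98) and 87689488 to 87689735 in WT cells (5.34). At Ccdc80 both had a peak inside the gene, at 45124598 to 45125100 on chromosome 16 in deficient cells (5.37) and 45124869 to 45125038 in WT cells (6.48). Deficient-cell peaks also lay inside Lgr6, Znrf3 and Sp5 and 4.14 kb from Lef1. WT peaks lay inside Lgr5 and 28.5 kb from Sp5. The WT peak near Sp5 had a fold enrichment of 5.88 (-log10 q 4.57), and the deficient-cell peak inside it 4.25 (-log10 q 1.89). The highest-scoring deficient-cell peak was inside Smad2, at 76289111 to 76289167 on chromosome 18 (fold enrichment 7.21, -log10 q 9.65), followed by 1 inside Bcas3.

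**Figure D5:**
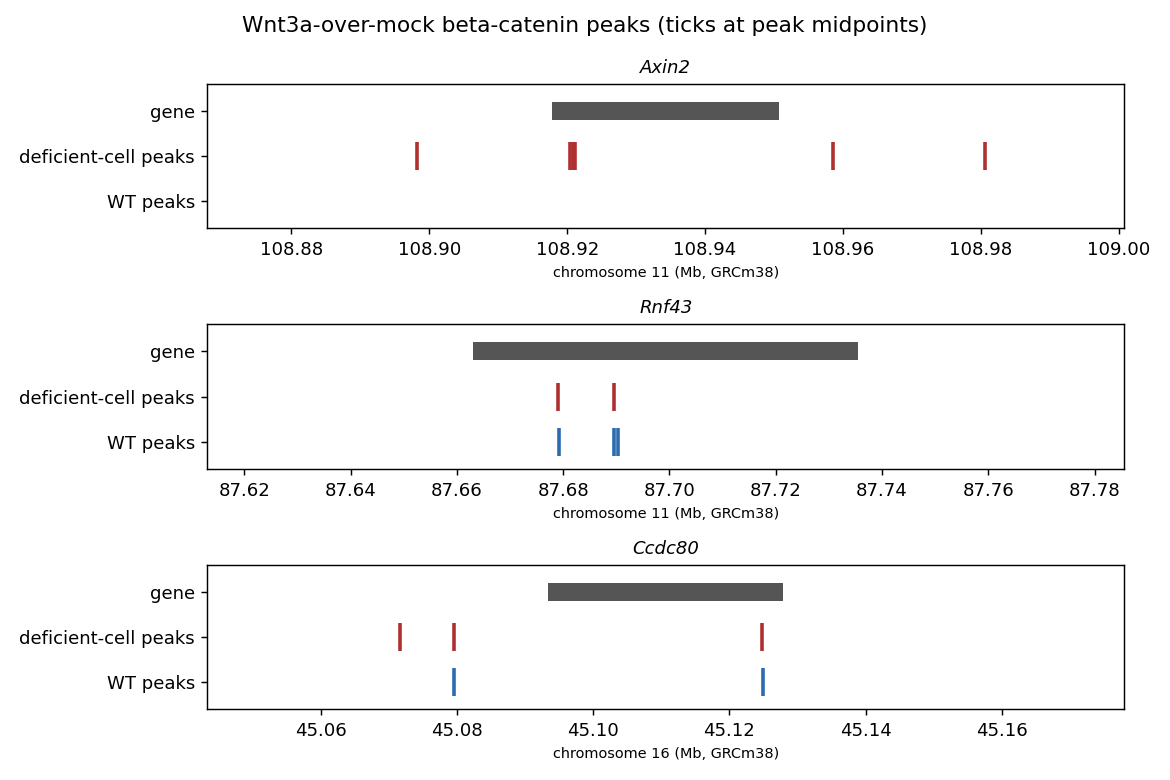
Positions of β-catenin peaks around Axin2, Rnf43 and Ccdc80 on GRCm38 (x axis, megabases); grey bars are the genes, red ticks deficient-cell peaks and blue ticks WT peaks, each at the peak midpoint. Axin2 has 6 deficient-cell and 0 WT peaks, Rnf43 has 2 and 3, and Ccdc80 has 3 and 2.

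Genes raised by Wnt3a lay near the peaks more often than other genes. Of 2430 genes raised in deficient cells, 349 (14.4%) had a deficient-cell peak within 50 kb, against 4.52% of other genes (odds ratio 3.55, Fisher's exact test, two-sided, adjusted p = 4.5e-60 over 16 tests). Of 358 genes raised in WT cells, 35 (9.78%) had a WT peak within 50 kb, against 1.03% (odds ratio 10.4, exact adjusted p = 4.9e-21). Genes are not independent, so the peaks were also shifted around each chromosome 1000 times. In this permutation test the shifts gave on average 137 and 4.35 genes, with a two-sided p = 0.002 in both cases, the smallest they can give (adjusted p = 0.0046). Nearness was not limited to the list of the same genotype or to Wnt3a. Of the 358 genes raised in WT cells, 88 (24.6%) had a deficient-cell peak (odds ratio 5.41). Of 4285 genes higher in deficient than WT mock cells, 381 (8.89%) had one, against 5.01% of other genes (1.85, shift adjusted p = 0.0046). Genes lower in deficient mock cells showed no such excess (0.716), nor did WT peaks near the higher ones (1.16, exact adjusted p = 0.45). Of 2423 genes lowered in deficient cells, 122 had a deficient-cell peak (odds ratio 0.782, exact adjusted p = 0.02, shift adjusted p = 0.17) and 12 a WT peak (0.352, exact adjusted p = 0.00014, shift adjusted p = 0.012). For the deficient-cell peaks the odds ratio depended on the setting, at 0.418 with the 50% of peaks that scored best by q (exact adjusted p = 3e-08), 0.835 within 100 kb (exact adjusted p = 0.028) and 1.01 within 10 kb (exact adjusted p = 1.0). For the WT peaks it was 0.367, 0.588 and 0.408 (exact adjusted p = 0.014, 0.0068 and 0.029). Of 288 genes lowered in WT cells, 27 had a deficient-cell peak (1.6, exact adjusted p = 0.034, shift adjusted p = 0.16) and 3 a WT peak (0.831, exact adjusted p = 1.0). The first of these had an exact adjusted p of 0.33 with the best-scoring 50%, 0.018 within 100 kb and 0.041 within 10 kb.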

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

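The thinning of libraries and the comparison of fold-change spreads were chosen after the gene counts they bear on were seen, with bounds set before their own outcomes; the splits of the samples were planned. The Wnt3a response differed between deficient and WT cells for 2131 genes by the test of the difference itself, and the values here are log2 differences, deficient minus WT. Among the genes named for this test, positive differences were found for Aldh1a2 (4.96), Tent5c (4.67), Rnf152 (4.56), Rnf43 (4.41), Efnb1 (3.14), Wnt7b (3.11), Tagln (3.07), Irx3 (2.99), Wnt9a (2.95) and Axin2 (2.48). Positive differences were also found for Cldn4 (2.14), Apcdd1 (1.78), Cdh6 (1.74), Fn1 (1.58), Twist1 (1.38), Mmp14 (1.36), Lgr6 (1.01), Hk2 (1.0) and Hnf1b (0.28). A positive difference need not mean a higher level under Wnt3a. Between mock groups Rnf43 (-4.61), Irx3 (-5.31) and Cdh6 (-4.66) were lower in deficient cells, while Axin2 (1.72) was higher. Negative differences were found for Ifi44 (-4.54), Enpep (-4.06), Cxcl5 (-3.56), Fat4 (-3.32), Cytip (-3.19), C3 (-2.69), Irf7 (-2.00), Rtp4 (-1.62), Ccl2 (-1.51), Kcnj16 (-1.41), Ggt1 (-1.36), Usp18 (-1.30), Id2 (-1.15), Insig1 (-0.53), Nphp1 (-0.40) and Bbs1 (-0.40). Leaving out deficient mock replicate 3 moved Rnf152 to 5.24 and Rnf43 to 5.06, and leaving out deficient Wnt3a replicate 2 moved Cytip to -4.08.

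More genes changed with Wnt3a in deficient cells (4987) than in WT cells (657). Deeper deficient-cell libraries do not account for it, since with all libraries thinned to the smallest total 4810 and 602 genes passed, a ratio of 7.99. Nor does a smaller spread between deficient-cell libraries, since the SD of fold changes over genes, net of sampling variance, was 0.447 in deficient and 0.162 in WT cells, a ratio of 2.76. Not every response was larger in deficient cells. Of the 657 genes that passed in WT cells, 353 had a larger fitted change in the same direction in deficient cells. These were 183 of the 363 raised and 170 of the 294 lowered. The sizes were compared without a test. Choosing genes that passed in WT cells favours large WT values, so this share may be too low. That the loss of HNF-1β may enlarge the response of many genes is a hypothesis from these data, and no value here tests it. A difference between the cell lines or clones other than HNF-1β stays open, since the labels do not part them; further deficient clones, or HNF-1β put back into these cells, would part them.

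Of the 10 splits of the 6 libraries of each comparison, 1, the real one, gave the highest count in every case, and 10 splits are too few for a share under 0.05. The real and highest other counts were 8539 and 0 for genotype in mock cells, 441 and 1 for Wnt3a in WT, 5243 and 1 for Wnt3a in deficient cells, and 9601 and 0 for genotype under Wnt3a. For the difference in response, 6 of 100 splits within genotypes, the real one included, gave at least 2131 genes, with 3383 the highest of the others. These splits mix mock and Wnt3a libraries within a genotype. With deficient groups real and WT groups mixed, a split still sets a full response against a mixed one. By the rule set beforehand, a share not under 0.05 goes with chance, and the share here was not under 0.05. Because of the mixed groups, this count cannot decide on chance for the difference, and does not exclude it. All 5 others kept the deficient-cell libraries in their real groups and mixed the WT libraries, which points to the large response of deficient cells as the structure behind them. The 90 splits that mixed the deficient-cell libraries gave at most 11.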

How the results depend on the processing

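The runs on thinned libraries, without chromosomes 16 and 18, without the mitochondrial chromosome, without 3 Wnt targets, with split WT mock libraries, and with all distances from peaks to gene intervals and circular shifts were chosen after seeing the data. RLE and upper quartile factors, DESeq2 and a filter at CPM of at least 1 in 3 libraries kept all 5 gene counts within 1.5 times (upper quartile factors shifted the balance to 2071 higher and 2905 lower for Wnt3a in deficient cells, and 922 and 1229 for the difference), and RLE, upper quartile and DESeq2 scaling moved the median of all genes by less than 0.1. A limit of 2-fold left 2688 genes for genotype in mock cells, 71 for Wnt3a in WT, 955 for Wnt3a in deficient cells, 3118 for genotype under Wnt3a and 533 for the difference in response, and glmTreat against 1.2-fold left 5646, 152, 1970, 6440 and 929; both ask for a larger change by construction. For Wnt3a in WT cells these were 56 higher and 15 lower, and 118 and 34, against 363 and 294. Without a filter on low counts the WT Wnt3a count was 986, and the cause was not tested. Leaving out 1 library gave 8399 to 8777, 428 to 633, 4073 to 4560, 9063 to 9326 and 1767 to 2022 genes, with fewer samples in each fit; the 428 came without WT mock replicate 2. A replicate block gave 9116, 701, 5116, 9738 and 2169 genes. Whether the numbers pair the libraries is not settled. Of 18 same-numbered pairs 4 correlated over 0.1, in a range of -0.12 to 0.20. By a strict rule, 0 of 12 libraries correlated best with their own number in every other group. Pairs of different numbers were not set beside these. With an estimated correlation the lists passing by camera went from 11 to 1 for genotype in mock cells. They went from 7 to 1 for Wnt3a in deficient cells, 12 to 4 for genotype under Wnt3a and 8 to 5 for the difference. Fry called 18, 16 and 20 lists in the first 3 of these comparisons, and asks another question. The cause of the drop with camera was not tested, but a correlation above the preset 0.01 is not behind every lost call. The list of secreted Wnt antagonists, for genotype in mock cells, lost its call at an estimate of -0.127. Mesenchymal genes, for Wnt3a in deficient cells, lost theirs at -0.015. Genes changed in the same direction by genotype and by Wnt3a in WT numbered 325, and 98, 117, 133, 187, 219 and 274 when the 3 shared mock libraries were split between the comparisons, with fewer samples in each. The share of WT peaks overlapping a deficient-cell peak was 33.3% at 50% reciprocal overlap, a stricter rule, against 64.7%. For 191 named values, 187 of them passing, 955 values under other settings were compared. Only the lowest and highest fold of each set of leave-one-out fits entered. Of the 955, 951 stayed on their side of the threshold, 3 passed newly, all for Ccdc80, and 1, for Znrf3 in WT cells, no longer passed. Among the 187 passing values 0 changed direction. For values that did not pass, a change of direction was not counted. Over all leave-one-out fits, Znrf3 lost its call in 5 of 6, and Ccdc80 passed in 1 of 6 for Wnt3a in WT cells and in 1 of 12 for the difference. The motif test was not run, as no genome sequence was at hand, and neither was the distance to transcription start sites. Depth limits genes near the floor, such as Ccdc80 with 3 counts in WT mock.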

Other observations

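All tests of chromosome shifts and the comparison of ChIP tag numbers were chosen or given their final form after the results were seen. The test of recurrent peak regions rests on distances and circular shifts also chosen after the data were examined, with its bound set before its own outcome. In deficient mock cells 8 of 13 kidney developmental transcription factor genes rose and 3 fell, as when adjusted over the list alone (camera adjusted p = 0.035, but adjusted p = 0.13 with an estimated correlation), with Irx1 (1.35) and Eya1 (1.06) higher. Under Wnt3a in deficient cells Irx2 rose (1.41) and Eya1 fell (-1.16), and the list did not pass (5 rose and 4 fell, 6 and 4 adjusted over the list alone, camera adjusted p = 0.85). Notch pathway genes went both ways in deficient mock cells, 3 up and 5 down of 15, as when adjusted over the list alone (camera adjusted p = 0.61). The receptor gene Notch1 (-1.90) and the ligand gene Jag1 (-2.33) fell there, and Notch3 rose with Wnt3a in deficient cells (2.31).

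Basement membrane genes also went both ways in deficient mock cells, 6 up and 10 down of 17, as when adjusted over the list alone (camera adjusted p = 0.52). Lama1 fell from 36.5 ± 0.0274 to 0.386 ± 0.135 CPM (-6.56 ± 0.14), while the collagen IV gene Col4a1 rose (1.26). The p53 target Cdkn1a, a cell cycle inhibitor gene, fell in deficient mock cells (-2.11) and rose with Wnt3a in them (1.23). The replication helicase gene Mcm3 rose (0.92), in a DNA replication list with 7 up and 8 down of 20, 8 and 8 adjusted over the list alone (camera adjusted p = 0.75). Of mitotic cell cycle genes 6 rose and 5 fell of 20, as when adjusted over the list alone (camera adjusted p = 0.84). The macrophage receptor gene Csf1r fell (-3.11). In the WT peak list the highest -log10 q values, 22.9 and 17.3, belonged to peaks inside the insulin genes Ins1 and Ins2, which are paralogs that can share reads, and 10 of the 201 WT peaks lay on the mitochondrial chromosome against 0 in deficient cells.

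Genes of chromosome 18 were lower in deficient cells, with a median log2 fold change of -0.52 (95% bootstrap interval -0.57 to -0.48), and genes of chromosome 16 higher, at 0.44 (0.31 to 0.63). Scaling of the libraries would shift other chromosomes as well, and the largest other median was -0.18, on chromosome 12. All 10 values of 20 Mb bins along chromosome 18, over both treatments, shared its sign at over 0.2, from -0.64 to -0.48, so a lower copy number of the whole chromosome is a candidate explanation. On chromosome 16 only 4 of 8 bin values did so, which argues against a gain of all of it, while the bins of its first 40 Mb were at 0.60 or above, so a gain of that part may be present. No DNA copy number was measured in the values used here.

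The deficient-cell peak list was longer than the WT list (1122 against 201 peaks), and most WT peaks were shared. Recurrent artefact regions were taken not to follow the Wnt3a response. Of the 130 shared peaks, 66 lay within 50 kb of a gene raised by Wnt3a in deficient cells. Circular shifts, 1000 in number, gave a mean of 18.9 and a highest value of 36 (permutation test, one-sided p = 0.001, the smallest they can give). The number lay above the bound set against artefacts. However, the shifts place peaks without regard to gene density, and the shared peaks were set beside no other genes. The test therefore cannot exclude artefacts in gene-rich regions as the source of the shared peaks, or of part of them. Near genes lowered by Wnt3a in deficient cells, the whole lists showed no excess of peaks within 50 kb (odds ratios 0.782 for deficient-cell and 0.352 for WT peaks). The WT peak inside Ins2 (-log10 q 17.3) was among the shared ones. More ChIP tags in deficient cells (a ratio of 1.11) cannot be excluded as part of the difference in peak number, since the pooled lists give no peak count at equal depth. More binding of β-catenin in deficient cells may also account for it, and the 1 pooled list per genotype leaves that untested.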
